A study of Mus musculus with 6 samples.

How the data were processed

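The labels describe keratinocytes scraped from trypsin-treated skin of mice aged 7 weeks, stained for CD34 and the alpha-6 integrin and sorted by flow cytometry into alpha-6+CD34+ and alpha-6+CD34- cells. Total RNA, 500 ng, was amplified and labelled with Cy3 or Cy5, and 750 ng of each labelled cRNA were hybridised for 17 hours to 60-mer arrays, per the labels. Each of the 3 biological replicates was hybridised on 2 arrays with the dyes exchanged. The labels number the replicate for 4 of the arrays, and the remaining 2, which have opposite dyes and no number, were taken as replicate 3 by elimination. Which dye held which population came from the labels of each array.

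The deposited scanner files hold 22393 features per array, of which 21318 are not controls. The intensity of each spot and of its local background was read from a scan with the Agilent Feature Extraction software, per the file headers. The deposited log10 ratios of Cy5 over Cy3 came from signals that the software had background-subtracted and dye-normalised, per the file headers. A p-value of each ratio from the software's own error model was also deposited, per the file headers, and lay under 0.01 for 15.2% to 22.4% of the features on an array. The headers name version A.6.1.1 of the software for the 2 arrays of replicate 3 and version A.7.5.1 for the 4 arrays of replicates 1 and 2, whereas the labels name a single version for all. The deposited value table of the series equals the negative of these log10 ratios, with a largest difference of 0, so its scale, centring and direction are known. Its column medians were 0.00257, 0, 0, 0.00274, 0 and 0.00187. Scan dates were not used here, and each array was on a slide of its own.

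From the mean and background intensities, limma 3.58.1 in R 4.3.3 corrected the background with normexp and an offset of 50 and normalised within arrays by loess, with control spots and spots marked as outliers by the software at weight 0. The sign of every log2 ratio was turned to CD34+ over CD34-. Spots of a probe were averaged, then the 2 arrays of a replicate, which hold the same extracts and count as 1 replicate. A probe entered if it was well above background in 1 population in at least 2 of the 3 replicates, which left out 472 of 20868 probes, and 182 more were left out for an outlier mark. A change on this scale is understated because of the offset, more so the dimmer the gene. In the simulation below, with genes changed at random, median found sizes were 0.827 to 0.836 of those given. Log2 ratios were tested against 0 with lmFit and eBayes, and a Benjamini-Hochberg adjusted p under 0.05 counted as passing. The pairing of the populations lies within each array and rests on the labels. The deviations of the CD34+ and CD34- channels of a replicate from their population means correlated across genes with r of 0.799, 0.717 and 0.811. Both channels are read from the same spots, so this correlation does not test whether the fractions came from the same animals.

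The scanner files name few genes by current symbols. Of 20868 probes, 8947 were named through their RefSeq accession in a table of assembly GRCm38.p6, 82 as list members by their description in the scanner file, 339 by a symbol and 273 by a synonym in that description, and 232 by the file's own symbol, which the table did not hold. The other 10995 stay unnamed, and 10603 of them were tested as probes. A gene was represented by its brightest probe. Of 122 genes with more than 1 tested probe, 29 passed by the brightest, 7 of these had another probe of opposite sign, and another probe passed in the same direction for 7 and in the opposite direction for 0. Of the genes that passed, 1 was not well above background on any array in CD34+ cells and 0 in CD34- cells, and no bound was needed for the genes named in the text.

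The lists of bulge markers, epidermal compartments, pathways and other cell types, the rule for named genes, the test and all but 1 of the alternatives were fixed before the data were examined. The rule named Cd34 and Itga6, the 10 largest rises and 10 largest falls among named genes that passed with the same sign on all 6 arrays, all passing bulge markers, and from each other list up to 2 rises and 2 falls, or the member with the smallest adjusted p where none passed. It gave 86 genes. Lists with at least 5 measured members were tested with camera at an inter-gene correlation of 0.01, adjusted over 26 lists, and again with an estimated correlation, on ranks, and with fry. With an estimated correlation camera takes its degrees of freedom from the 3 replicates, which leaves it little power. A list that does not pass there is therefore not shown to be unchanged. Member counts are given over all genes tested and adjusted over the list alone.

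Alternatives changed the source of the ratios, the background offset, the normalisation, the filter on dim probes, the treatment of outlier spots and of several probes of a gene, the dye orientation, the replicate block, the variance prior, the threshold and the replicates used. The version of the extraction software as a batch term was added after seeing the data. It sets replicate 3 against replicates 1 and 2, so the spread then comes from replicates 1 and 2 alone, and the batch of replicate 3 holds 1 replicate, for which no test within the batch exists.

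The steps were tested on simulated spots for the comparison of CD34+ with CD34- cells over 20090 genes, of which 200 were changed at random and 1 list was shifted. Of the changed genes, 32.8% were recovered at a log2 change of 0.5, 89.6% at 1 and 98.5% at 2, with found sizes of 0.827, 0.836 and 0.833 of those given. Of 19854 unchanged genes 17 were called, 8.90% of the calls, a larger share than the adjusted p threshold aims at. The shifted list passed with 0 others. That result is no check on the 8 lists that passed in the real data. Noise between simulated replicates was drawn for each spot on its own, without correlation between genes, and alike for all replicates. Far fewer genes were changed than the 2419 that passed in the real data. The shares recovered and wrongly called hold for that setting only. In the real data 0 of the 8 lists passed with an estimated correlation. Before loess the ratios of the 2 arrays of a replicate correlated with r of 0.697, 0.680 and 0.342, and after it with 0.859, 0.910 and 0.673. The 2 arrays of a replicate differed by more than 1.5 in log2 for 51 genes in replicate 1, 3 in replicate 2 and 79 in replicate 3, of which 2, 0 and 2 passed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.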

Results

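Gene expression was measured on 6 oligonucleotide arrays of 2 colours in keratinocytes from the skin of adult mice, 7 weeks old. Cells that carried the alpha-6 integrin, a receptor of basal keratinocytes that anchors them to the basement membrane, were sorted into a fraction with the surface protein CD34 and a fraction without it. CD34 marks the stem cells of the hair follicle bulge in mice, and the labels call the CD34+ fraction stem and progenitor cells and the CD34- fraction basal cells. Both fractions came from 3 biological replicates. Within each replicate they were hybridised against each other on 2 arrays with the dyes exchanged, so n = 3 throughout. Between 92.9% and 97.7% of the probes lay well above background in a population on an array. That mark is a signal above background and is no evidence by itself that a gene is expressed. The number of arrays limits the precision of every value. All changes are log2 ratios of CD34+ over CD34- cells, averaged over the replicates and given ± SD, and all p-values of genes come from limma with Benjamini-Hochberg adjustment. A range in brackets after a list median runs over all alternatives. Positions in the genome were not used here.

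Cd34, the gene of the protein used for the sort, was higher in CD34+ cells by 5.84 ± 0.43 (SD, n = 3), a 57.3-fold difference with an adjusted p of 0.00367, and it was higher on 6 of 6 arrays. This value checks the labels and the direction of the dyes and is no finding. Itga6, the alpha-6 integrin that both fractions were gated on, fell by 1.18 ± 0.27 (SD, n = 3) in CD34+ cells, with an adjusted p of 0.0181 and a lower signal on 6 of 6 arrays. The other Itga6 probe was lower too, at -0.79 ± 0.16, with an adjusted p of 0.0180. Without replicate 1 the adjusted p was 0.0903 for both genes, with changes of 5.85 and -1.33. Without replicate 2 it was 0.0625 for Itga6, with a change of -1.10. With the populations fitted as unpaired channels, without the replicate block, it was 0.0826 for Itga6.

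The comparison asked which genes set the CD34+ keratinocytes apart from the alpha-6+CD34- keratinocytes, which the labels call basal cells. The rises and falls here are the largest among the genes that the rule could name, which leaves out unnamed probes. After Cd34, the largest rise in CD34+ cells was that of Tbx1, a T-box transcription factor, at 4.61 ± 0.31. Dkk3, a secreted protein of the Dickkopf family, followed at 4.48 ± 0.30 (SD, n = 3, adjusted p 0.00359 for both). Ccn2, a matricellular protein also known as connective tissue growth factor, rose by 3.99 ± 0.27, and Ltbp2, a latent TGF-beta binding protein, by 3.85 ± 0.41. Lhx2, a LIM-homeobox transcription factor of hair follicle stem cells, rose by 3.75 ± 0.15. Calml3, a calmodulin-like protein of epithelia, rose by 3.65 ± 0.26, and the matricellular protein Postn by 3.49 ± 0.22. Thsd1, a membrane protein with a thrombospondin domain, and Mfge8, a secreted protein that binds phosphatidylserine, both rose by 3.30, with SDs of 0.44 and 0.51. These 9 genes had adjusted p-values between 0.00359 and 0.0108.

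Among the genes that the rule could name, the largest fall in CD34+ cells was that of Tnfrsf19, at -2.77 ± 0.92 (SD, n = 3, adjusted p 0.0254). Tnfrsf19 is a receptor of the TNF receptor family. Plbd1, a phospholipase B-like protein, fell by 2.58 ± 0.99, and Il33, a cytokine stored in the nuclei of epithelial cells, fell by 2.55 ± 0.69. Slc22a4, a transporter of organic cations, fell by 2.44 ± 0.83, and Tppp3, a tubulin-binding protein, by 2.34 ± 0.80. Ly6c1, a surface protein of the Ly6 family, fell by 2.29 ± 0.66, and Clca3a2, of the chloride channel accessory family, by 2.25 ± 0.96. Klf5, a zinc-finger transcription factor, fell by 2.18 ± 0.69. Adam8, a membrane-bound metalloprotease, fell by 2.14 ± 0.58 on its brightest probe, and its other probe gave -0.69 ± 0.21 with an adjusted p of 0.0262. Krt1, a keratin of suprabasal cells, fell by 2.28 ± 1.10 with an adjusted p of 0.0466 on its brightest probe, whereas its other probe gave 0.17 ± 0.080 with an adjusted p of 0.121.

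**Figure D1:**
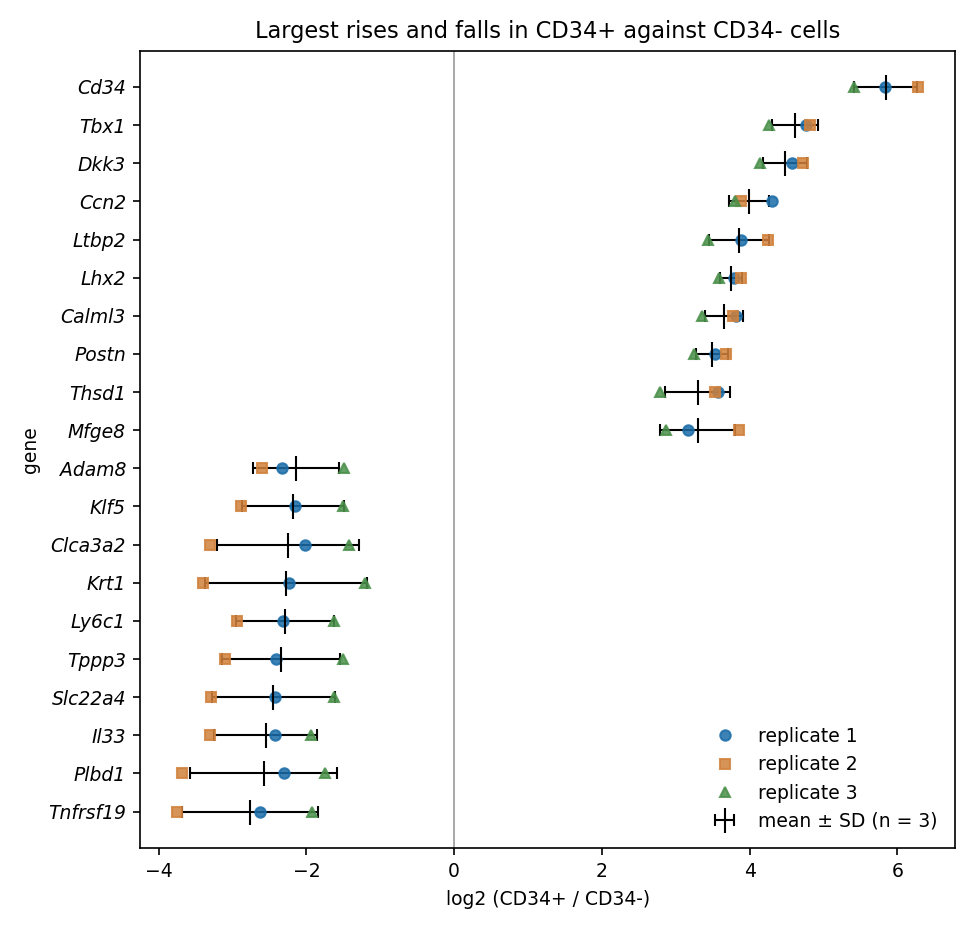
The 10 largest rises and 10 largest falls named by the rule, with the log2 ratio of CD34+ over CD34- cells on the x axis and genes on the y axis; coloured symbols are the 3 replicates, and black bars are the mean and SD (n = 3). The rises run from 3.30 for Mfge8 to 5.84 for Cd34, and the falls from -2.14 for Adam8 to -2.77 for Tnfrsf19.

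Of 20090 genes and unnamed probes tested, 2419 passed an adjusted p of 0.05, of which 1085 were higher and 1334 lower in CD34+ cells. Among the 9487 named genes, 558 rose and 763 fell. A change of at least 2-fold was reached by 255 of the rises and 241 of the falls, and of at least 4-fold by 56 rises and 20 falls. The sign was the same on all 6 arrays for 2387 of the 2419, or 98.7%. These genes were called from the means of the same arrays, so that share is no separate support for the calls. The count rested on which replicates entered. Without replicate 1, limma called 0 genes, with 4621 at an unadjusted p under 0.05. Without replicate 2 it called 299, and without replicate 3 it called 4198. With the populations as unpaired channels, without the replicate block, 550 genes passed.

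Markers of the bulge, the hair follicle niche of stem cells, rose together in CD34+ cells. Of the 27 members measured, 17 rose, 0 fell and 10 did not pass, and 22 rose when adjusted over the list alone. The members that rose included Dkk3, Ccn2, Lhx2 and Postn, given above, and Lgr5, a receptor for R-spondins found on cycling follicle stem cells, at 2.73 ± 0.62 (SD, n = 3, adjusted p 0.0169). Fgf18, a growth factor of the resting bulge, rose by 2.53 ± 0.38, the secreted Wnt antagonist Sfrp1 by 2.44 ± 0.13, and Id2, an inhibitor of basic helix-loop-helix factors, by 2.19 ± 0.53. The matrix glycoprotein Tnc rose by 2.17 ± 0.45 and the growth arrest gene Gas1 by 1.91 ± 0.53. The transcription factors Tcf7l1 and Nfatc1, both known from bulge stem cells, rose by 1.63 ± 0.40 and 1.16 ± 0.22. Smaller rises were those of Ltbp1 at 1.06, Eps8 at 0.96, Gsn at 0.91, Cdkn1c at 0.51 and Cd200 at 0.36. On the deposited ratios, which carry no offset, Ltbp1 was at 1.75, Eps8 at 2.03, Cdkn1c at 0.77 and Cd200 at 0.85, and with median centring Gsn lost its call at 0.43 and an adjusted p of 0.210. Krt15, a keratin used as a bulge marker and singled out after its value was seen, was at 0.77 ± 0.52 with an adjusted p of 0.0935. The bulge median was 0.96, with replicate medians of 1.17, 1.18 and 0.89, and 1.47 with an offset of 0, and camera gave it an adjusted p of 6.57e-14 (adjusted p = 0.570 with an estimated correlation).

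Cell cycle genes were lower in CD34+ cells. Of 36 measured, 0 rose, 24 fell and 12 did not pass, and adjusted over the list alone 1 rose and 28 fell. Cdc20, an activator of the anaphase-promoting complex, fell by 2.03 ± 0.51, and the proliferation marker Mki67 fell by 1.87 ± 0.51 (SD, n = 3, adjusted p 0.0191 and 0.0203). The cell cycle median was -0.77 (-0.96 to -0.64), with replicate medians of -0.73, -0.95 and -0.54, and a camera adjusted p of 6.85e-13 (adjusted p = 0.570 with an estimated correlation). Among 9 CDK inhibitors and pocket proteins, which hold back the cell cycle, 1 rose and 3 fell, against 2 and 4 adjusted over the list alone. Cdkn1c, the inhibitor p57, rose by 0.51 ± 0.14, while the INK4-family inhibitors Cdkn2d and Cdkn2c fell by 0.87 ± 0.064 and 0.38 ± 0.093. That list did not pass as a set, with a median of -0.092 (-0.21 without replicate 1 to -0.020 without replicate 3) and a camera adjusted p of 0.285.

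Genes of MHC class I and antigen processing, which present peptides to T cells, were lower in CD34+ cells. Of 16 measured, 0 rose, 12 fell and 4 did not pass, and 14 fell when adjusted over the list alone. Psmb8 and Psmb9, subunits of the immunoproteasome, fell by 1.68 ± 0.58 and 1.43 ± 0.46 (SD, n = 3, adjusted p 0.0272 and 0.0250). The MHC class I median was -1.01 (-1.17 to -0.83), with replicate medians of -0.97, -1.38 and -0.64, and a camera adjusted p of 6.12e-08 (adjusted p = 0.570 with an estimated correlation). In fry the list had an adjusted p of 0.0888. Markers of the skin's immune cells did not pass as sets with all replicates. Of 19 Langerhans cell markers, 1 rose and 1 fell, against 1 and 0 adjusted over the list alone. The rise was that of Mfge8, and the fall that of Tyrobp, an adaptor protein of myeloid cells, at -0.24 ± 0.046, or -0.62 on the deposited ratios, a call that 9 of 18 alternatives ended. Their median was -0.086 (-0.13 to -0.018) and their mean 0.091, and camera, with the sign of the median, gave an adjusted p of 0.432. Of 23 T cell markers, 1 rose and 0 fell, against 0 and 0 adjusted over the list alone. Il2rb, a chain of the interleukin-2 receptor, rose by 0.28 ± 0.069, a call that 9 of 18 alternatives ended. The T cell median was 0.021 (0.018 to 0.090), with a camera adjusted p of 0.153, and without replicate 2 the list was higher in CD34+ cells, with a median of 0.066 and an adjusted p of 0.0289.

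Genes of the extracellular matrix and basement membrane were higher as a set in CD34+ cells. Of 42 measured, 17 rose, 2 fell and 23 did not pass, against 20 and 5 adjusted over the list alone. The list shares 3 members with the bulge markers, and Postn and Tnc, which belong to both, had its largest rises, while Efemp1 and Thbs2, secreted matrix glycoproteins, fell by 2.09 ± 0.43 and 1.73 ± 0.10 (SD, n = 3, adjusted p 0.0152 and 0.00456). The list's median was 0.11 (0.10 to 0.19, the latter with CD34+ in Cy3 only), with replicate medians of 0.17, 0.12 and 0.15, and a camera adjusted p of 0.00300 (adjusted p = 0.570 with an estimated correlation). Fibroblast markers were higher as a set in camera too, with 6 of 21 that rose and 1 that fell, the same counts adjusted over the list alone, and 6 members belong to the matrix list too. Fstl1, a secreted follistatin-like glycoprotein, rose by 1.92 ± 0.23 and the matrix protein Fbln1 by 1.80 ± 0.23, while Pcolce, an enhancer of collagen processing, fell by 0.36 ± 0.091, a call that 6 of 18 alternatives ended. Col3a1, an abundant collagen of fibroblasts singled out after its value was seen, was at 0.018 ± 0.070 with an adjusted p of 0.834. The fibroblast list had a median of 0.074 (0.066 to 0.28, the latter on the deposited ratios) and a camera adjusted p of 0.0333 (adjusted p = 0.570 with an estimated correlation), a call that other settings ended. The adjusted p was 0.0544 without replicate 1, 0.109 with CD34+ in Cy5 only, 0.0953 with CD34+ in Cy3 only, 0.0529 with scaling between arrays and 0.0713 on ranks. It was 0.0515 with 6 arrays and a dye term, and 0.0644 with the software version as a batch term.

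The BMP and TGF-beta pathway, a family of secreted signals with its receptors and inhibitors, was higher as a set in CD34+ cells, next to a fibroblast marker median of 0.074. Of 44 members, 15 rose, 3 fell and 26 did not pass, against 18 and 7 adjusted over the list alone. The list shares 5 members with the bulge markers, Id2 and Ltbp1 among them. Ltbp2 and Id2, given above, led the rises, and the ligands Bmp4 and Bmp7 fell by 1.33 ± 0.32 and 1.00 ± 0.47 (SD, n = 3, adjusted p 0.0189 and 0.0464). The list's median was 0.083 (0.071 to 0.16, the latter with an offset of 0), with a camera adjusted p of 0.0167 (adjusted p = 0.570 with an estimated correlation), which was 0.0587 with CD34+ in Cy3 only and 0.0593 on ranks. Among 14 genes of integrins and the hemidesmosome, the junction that ties basal cells to the basement membrane, 5 rose and 1 fell, the same counts adjusted over the list alone. Col17a1, a transmembrane collagen of the hemidesmosome, rose by 0.67 ± 0.14 and the tetraspanin Cd151 by 0.54 ± 0.093, and the fall was that of Itga6. The integrin list had a median of 0.17 and a camera adjusted p of 0.0462 (adjusted p = 0.570 with an estimated correlation), which was 0.0544 without replicate 1, at a median of 0.27, and 0.137 without replicate 3. With median centring in place of loess it was 0.154, with CD34+ in Cy3 only 0.343, at a median of 0.10, and over the 7 other settings that ended the call between 0.0511 and 0.0854. The median was 0.32 with an offset of 0 and 0.35 on the deposited ratios.

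Early response genes, which are induced within minutes of a stimulus such as cell dissociation, were lower as a set in CD34+ cells. Of 30 measured, 4 rose, 6 fell and 20 did not pass, against 5 and 14 adjusted over the list alone. The zinc-finger factor Klf6 and the stress-induced factor Atf3 both fell by 1.09, with SDs of 0.24 and 0.29 (n = 3, adjusted p 0.0177 and 0.0209). The kinase Sgk1 and the growth arrest gene Gadd45g rose by 1.05 ± 0.37 and 0.91 ± 0.15. The list's median was -0.49 (-0.64 to -0.36), with replicate medians of -0.66, -0.55 and -0.068. Its camera adjusted p was 0.0415 (adjusted p = 0.708 with an estimated correlation), and 0.241 without replicate 1. It was 0.0822 with scaling between arrays, 0.171 with CD34+ in Cy3 only, 0.0593 on ranks and 0.288 in fry.

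Wnt, Notch, Hedgehog and ephrin genes did not pass as sets in camera, although single Wnt, Notch and Hedgehog genes rose or fell. In the Wnt pathway 7 of 40 rose and 4 fell, against 12 and 8 adjusted over the list alone. Dkk3 and Sfrp1 rose, as given above, and the ligands Wnt3 and Wnt10a fell by 1.84 ± 0.50 and 1.76 ± 0.41 (SD, n = 3, adjusted p 0.0202 and 0.0181). The Wnt list had a median of 0.043 (0.032 to 0.066), a camera adjusted p of 0.322 and a fry adjusted p of 0.0140. In the Notch pathway 2 of 22 rose and 3 fell, against 4 and 4 adjusted over the list alone. The receptor Notch1 and its ligand Dll1 fell by 1.30 ± 0.20 and 0.76 ± 0.31, while Numbl, of the Numb family, and the transcriptional regulator Hes6 rose by 1.07 ± 0.16 and 0.51 ± 0.11. The Notch list had a median of -0.018 (-0.049 to 0.021, the latter with median centring) and a camera adjusted p of 0.572. In the Hedgehog pathway 3 of 14 rose and 0 fell, the same adjusted over the list alone, among them Gas1 and the transcription factor Gli2, which rose by 0.57 ± 0.13. Its median was 0.082 (0.026 to 0.14) and its camera adjusted p 0.153, which was 0.0438 without the replicate block, and its fry adjusted p was 0.0342. Of 15 Eph and ephrin genes 0 passed in limma, over all genes or adjusted over the list alone, and 5 had an unadjusted p under 0.05. The smallest adjusted p was that of Efna1, 0.0576 at 0.24 ± 0.075, and the list's camera adjusted p was 0.322 at a median of 0.040 (0.027 to 0.13).

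Other compartments of the epidermis did not pass as sets in camera either. Of 16 interfollicular and infundibular basal markers, 2 rose and 3 fell, against 4 and 6 adjusted over the list alone. Ly6c1 fell, as given above, and Ly6a, also known as Sca-1, fell by 1.60 ± 0.27, while the Wnt and BMP modulator Sostdc1 and the proteoglycan Sdc1 rose by 0.88 ± 0.21 and 0.72 ± 0.19 (SD, n = 3). That list's median was -0.46 (-0.58 to -0.18, the latter without replicate 2), with replicate medians of -0.30, -0.59 and -0.052. Its camera adjusted p was 0.322, which was 0.0438 without the replicate block. Of 23 suprabasal differentiation genes, 2 rose and 2 fell, the same adjusted over the list alone. Lor, a protein of the cornified envelope, rose by 1.51 ± 0.18 and the transcription factor Klf4 by 0.91 ± 0.23, a call lost with median centring at 0.48 and an adjusted p of 0.0600, while Krt1 and the desmosomal cadherin Dsg1a, at -0.43 ± 0.17 or -0.85 on the deposited ratios, fell. The suprabasal median was -0.062 (-0.19 to -0.035) with a camera adjusted p of 0.412, and without replicate 3 these were -0.19 and 0.0377. Of 12 basal keratinocyte genes, the integrin chain Itgb4 rose by 0.38 ± 0.094, a call lost with median centring at 0.15 and an adjusted p of 0.523, and the desmosomal protein Dsp fell by 0.41 ± 0.16, with -0.75 on the deposited ratios. Adjusted over the list alone, 4 rose and 1 fell, and the median was 0.10 (0.054 to 0.15) with a camera adjusted p of 0.311 and a fry adjusted p of 0.0353.

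Hair shaft and inner root sheath genes held 3 rises and 1 fall among 18, against 5 and 1 adjusted over the list alone. The homeobox gene Msx2 and the hair keratin Krt33a both rose by 0.44, with SDs of 0.13 and 0.18, and the transcription factor Gata3 fell by 1.75 ± 0.45 (n = 3, adjusted p 0.0194). The median was 0.049 (0.049 to 0.11) with a camera adjusted p of 0.322 and a fry adjusted p of 0.0226. Of 18 sebaceous gland genes, 2 rose and 0 fell, the same adjusted over the list alone. They were Elovl5, an elongase of polyunsaturated fatty acids, at 1.33 ± 0.50, and the glutathione transferase Mgst1, at 0.50 ± 0.22, a call that 7 of 18 alternatives ended. The sebaceous median was 0.028 with a camera adjusted p of 0.458. Without replicate 2 these were 0.076 and 0.0111, and without replicate 3 the median turned to -0.027. Of 17 cholesterol synthesis genes, 1 rose and 2 fell, against 1 and 4 adjusted over the list alone. Sqle, the squalene epoxidase, rose by 0.43 ± 0.13, and the enzymes Hsd17b7 and Sc5d fell by 0.97 ± 0.042 and 0.47 ± 0.031. The cholesterol median was -0.049 (-0.24 to -0.031) with a camera adjusted p of 0.322.

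Apart from the fibroblast markers, markers of other cells that a skin preparation could hold did not pass as sets in camera with all replicates. Of 13 melanocyte markers, 3 rose and 1 fell, the same adjusted over the list alone. Mitf and Dct, a transcription factor and an enzyme of pigment cells, rose by 0.99 ± 0.31 and 0.79 ± 0.29, and Rab38, a GTPase of melanosome transport, fell by 0.65 ± 0.092 (SD, n = 3). The median was 0.032 (0.0019 to 0.065) with a camera adjusted p of 0.380. Of 15 endothelial markers only Egfl7 rose, by 0.44 ± 0.082, also adjusted over the list alone, and the median was 0.0018 (-0.00010 to 0.052) with a camera adjusted p of 0.412. Of 13 Schwann and nerve markers 1 rose, Cnp, at 0.35 ± 0.14, a call that 10 of 18 alternatives ended, against 0 adjusted over the list alone, and the median was 0.0039 (-0.019 to 0.045) with a camera adjusted p of 0.412. Of 9 Merkel cell markers 1 rose, also adjusted over the list alone, the keratin Krt8, at 0.27 ± 0.062, a call that 7 of 18 alternatives ended. The Merkel median was -0.041 (-0.092 to 0.059, the latter with median centring) and the mean 0.013, and camera, with the sign of the median, gave an adjusted p of 0.972. Of 14 muscle markers 1 fell, the cardiac actin Actc1, at -0.56 ± 0.18, against 1 rise and 4 falls adjusted over the list alone, and the median was -0.071 (-0.22 to -0.029) with a camera adjusted p of 0.131 and a fry adjusted p of 0.0345.

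**Figure D2:**
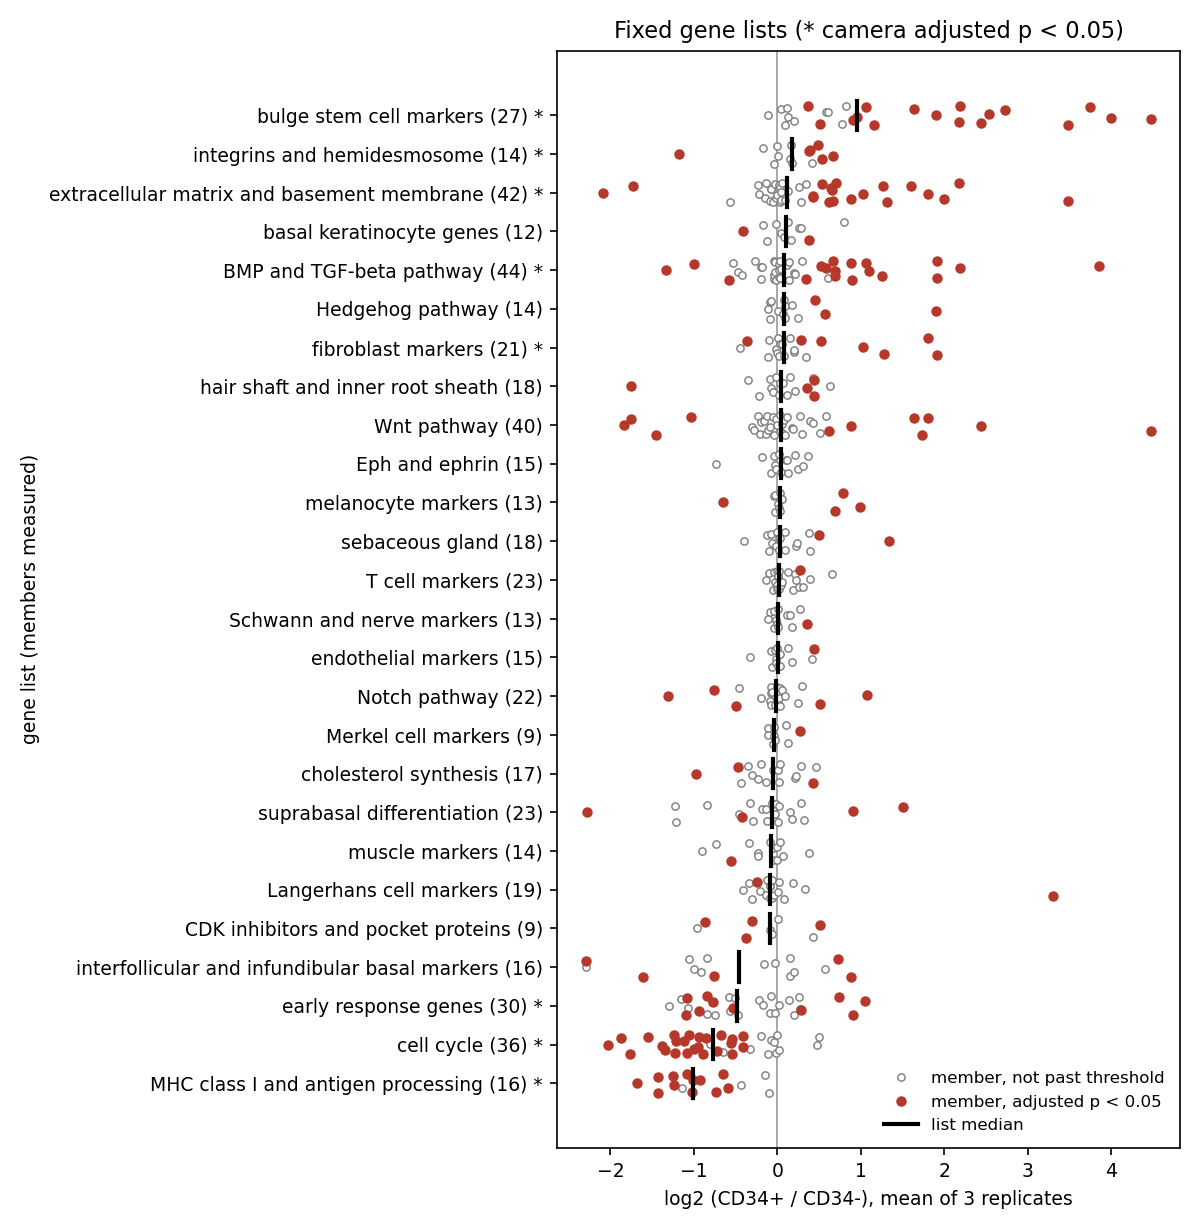
The 26 gene lists on the y axis, with the number of members measured, and the log2 ratio of CD34+ over CD34- cells on the x axis; each circle is a member's mean of 3 replicates, filled where its adjusted p was under 0.05, and black lines are list medians. The medians run from -1.01 for MHC class I and antigen processing to 0.96 for the bulge stem cell markers, and asterisks mark the 8 lists with a camera adjusted p under 0.05.

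Across the replicates, changes correlated over genes with r of 0.911 between replicates 1 and 2, 0.685 between 1 and 3, and 0.757 between 2 and 3. These are correlations across genes, which are not independent replicates. Of the 26 lists, 8 passed, 5 higher and 3 lower in CD34+ cells. With an estimated correlation 0 of the 26 passed, also at an unadjusted p under 0.05. The lowest unadjusted camera p there was 0.0533, for the matrix list. With 3 replicates that test has little power, so it does not decide whether the 8 lists changed. Without replicate 1, 5 lists passed, and without replicate 2, 10. Fry asks whether a list's genes move on balance in 1 direction and does not compare them with other genes. It passed 11 lists, 9 higher and 2 lower, of which 6 were among the 8.

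**Figure D3:**
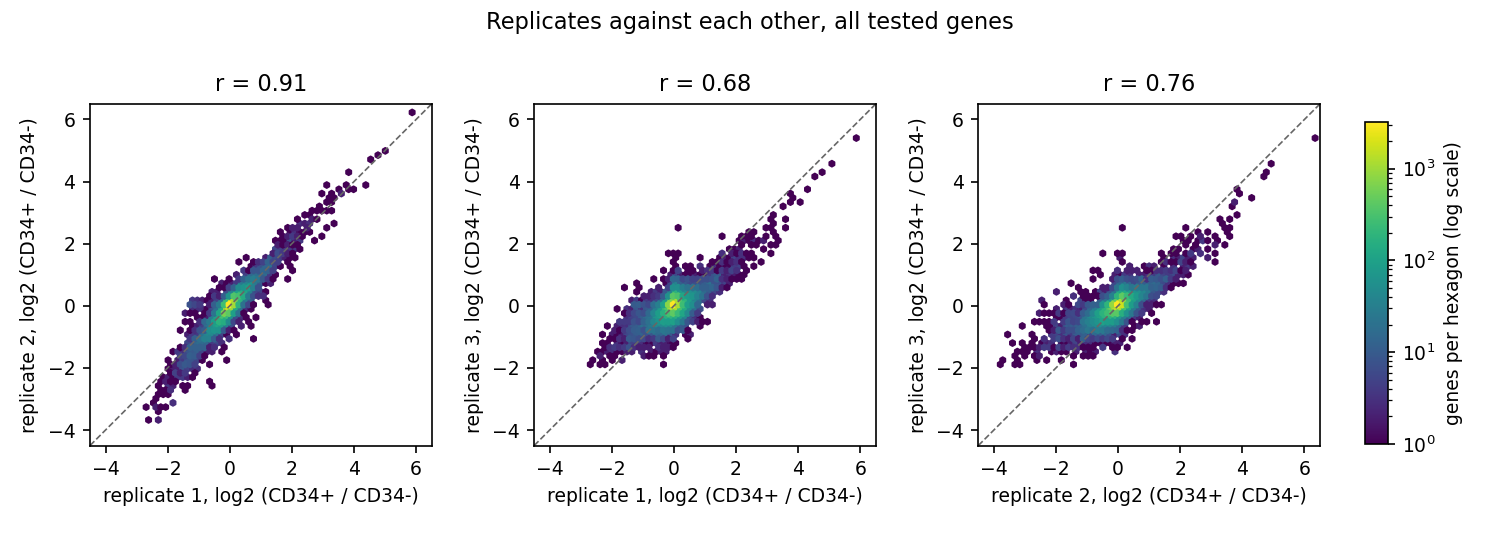
Log2 ratios of CD34+ over CD34- cells in pairs of replicates, 1 replicate on each axis, over the 20090 genes and probes tested, with colour for the number of genes in a hexagon on a log scale; the dashed line marks equal values. Replicate 3 lies closer to 0 than replicates 1 and 2 at both ends, with an SD over genes of 0.33 against 0.39 and 0.45.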

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

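All alternatives were planned except the batch term for the extraction software, chosen after seeing the data. The count of 2419 genes stayed within 1.5 times under 12 of 20 alternatives, from 1786 with scaling between arrays to 3220 with CD34+ in Cy5 only. The software's own ratios and the deposited value table are the same data entered as separate alternatives, each with 2527 genes. Tallies over alternatives, here and above, therefore count that fit more than once. Without the replicate block, and so without the pairing, 550 genes passed, 550 of them among the 2419. A fit that kept the pairing but took the 6 arrays singly, with the replicate as a random block and a dye term together, gave 4259. The batch term gave 5310. A 2-fold minimum left 496 and an adjusted p under 0.01 left 89. Leaving out each replicate in turn gave 0 to 4198, with fewer samples by construction; the 0 came without replicate 1, where limma had 4621 at an unadjusted p under 0.05. Of the other alternatives' shifts the cause was not tested. The 8 lists became 5 with scaling between arrays, 4 with CD34+ in Cy3 only, 4 with camera on ranks and 0 with an estimated correlation, and 5 to 10 without a replicate. Fry passed 11, of which 6 were among the 8; it lost MHC class I (0.0888) and early response genes (0.288) and added Wnt (0.0140), Hedgehog (0.0342), basal keratinocyte (0.0353), hair shaft (0.0226) and muscle genes (0.0345), each an adjusted p. Cd34 was 5.62 to 6.05 without a replicate, with adjusted p from 2.0e-05 to 0.0903 over all alternatives. Itga6 was -1.33 to -1.10 without a replicate and -1.18 without the replicate block, with adjusted p from 0.00193 to 0.0903. Among the other 84 named genes over 18 alternatives, 1285 of 1512 values kept their direction and side of the threshold, 224 lost the call, 3 gained it and 0 turned sign; 83 of the losses came without replicate 1, 43 without replicate 2, 41 without the replicate block, 16 with scaling between arrays and 13 with median centring. Of 546 list tests, 502 kept their side of the threshold, 34 lost and 10 gained the call. The sign of a list median turned in 7 of them, over 5 lists that did not pass: Merkel cell and Notch (median centring, 0.059 and 0.021), Notch (stricter filter, 0.0013), Schwann (CD34+ in Cy3 only, -0.019), and Schwann, sebaceous and endothelial markers (without replicate 3, -0.0064, -0.027 and -0.00010). On each array 92.9% to 97.7% of probes lay well above background, and the offset compresses changes, most of all those of the dim probes.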

Other observations

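The tests on replicate 3, on immune cells and on dye bias at Itga6 were chosen only after the result was seen, and the test of the other Itga6 probe and the counts with a replicate's sign turned were chosen before.

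Genes were also compared between the dyes, apart from the populations. A dye effect passed the threshold for 2982 genes, of which 1402 were brighter in Cy5, and the consensus correlation of the 2 arrays of a replicate was 0.667. Turning the sign of 1 replicate, each once, makes 4 choices with the real one, too few for a share under 0.05, and 1 of the 4, the real one, gave as many genes. The real signs gave 2419 genes and the highest other choice 0. For the lists the real signs gave 8 and the highest other choice 5, and again 1 of the 4 gave as many.

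Changes were smaller in replicate 3 than in replicate 1. Over 142 rises and 90 falls chosen on replicate 1, beyond 1.5 in log2, the median ratio of replicate 3 to replicate 1 was 0.711 (quartiles 0.586 to 0.849) for rises and 0.625 (quartiles 0.422 to 0.737) for falls, against 1.03 and 1.23 for replicate 2. CD34+ cells in the CD34- sample of replicate 3 were argued against for the rises: Cd34 allows a share of at most 2.34%, which gives a ratio of 0.951. For the falls, mixing of CD34- cells into its CD34+ sample at 24.2%, the share that gives their median, predicts 0.588 for the 23 deepest and 0.643 for the 23 shallowest. The observed medians, 0.673 (quartiles 0.602 to 0.728) and 0.527 (quartiles 0.303 to 0.751), run in the opposite order. Mixing stays open for the falls all the same, because the quartiles overlap. A share of 17.8%, chosen on the deepest falls, gives 0.674 and 0.725, both within them. What this mixing would do to the rises was not computed. Replicate 2, with genes chosen on replicate 1 likewise, had the same order, 1.27 and 1.14, and no fall of replicate 3 passed the floor of -2.05 that 24.2% sets, the deepest being Il33 at -1.93. A single factor on all ratios, from the scanner, the software version or the background, cannot be told apart from a difference between the animals, since the software version is confounded with this replicate and the ratios of falls, 0.625, and of rises overlap.

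MHC class I genes were lower in CD34+ cells, with a list median of -1.01. The list did not pass in camera with an estimated correlation (adjusted p = 0.570) or in fry (adjusted p = 0.0888). A candidate source was immune cells in the CD34- sample, although both fractions were gated on the alpha-6 integrin. The 8 Langerhans cell markers brighter than the median gene in CD34- cells had a median of -0.049, with a median absolute deviation of 0.197, and ran from -0.42 for Cd74 to 3.30 for Mfge8, with Cd207 at -0.14. The 6 such T cell markers had a median of 0.052, with a median absolute deviation of 0.0762. Of the 14, 0 fell by as much as the MHC class I median. This would argue against both cell types as the whole source only where the markers' signal came from such cells. Brightness alone does not show that, and Mfge8 was higher in CD34+ cells, so neither cell type is excluded. A lower level of MHC class I genes in the CD34+ keratinocytes themselves is a hypothesis found on these data and was not tested directly. Other immune cells were not tested either.

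Itga6 was lower in CD34+ cells although both fractions were gated on its protein. A fault of 1 probe was argued against by the other Itga6 probe, at -0.79 with an adjusted p of 0.0180, and dye bias by a lower signal on 6 of 6 arrays, 3 in each orientation. A difference in how bright the sorted cells of each fraction were for the alpha-6 integrin stays open, because no sort intensities were used here. A lower Itga6 transcript in CD34+ cells may be the biological counterpart and was not tested apart from this.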
